A study of Mus musculus with 6 samples.

How the data were processed

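Gene expression was measured by RNA sequencing of splenic CD4+ T cells from 6 female C57BL/6 mice, 3 control mice and 3 mice given angiotensin II. Per the labels' protocols, cells were taken with a magnetic CD4 isolation kit, RNA was extracted from them, and libraries were made with an Illumina TruSeq kit. Per the submitters' processing notes, the tools used were Trimmomatic 0.32 (read trimming), TopHat2 2.1.1 (alignment) and Cuffdiff, with the mouse genome build GRCm38.p3. The version of Cuffdiff, the annotation release, and the program and settings behind the library files are not given in the sources used here.

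The authors deposited 1 file per library with FPKM (fragments normalised to transcript length and library size) for 39171 Ensembl gene identifiers. The authors' deposited table of the whole series gives, per the file headers, a p-value and a q-value for each gene from the authors' own comparison of 2 conditions. Its header has the layout of a Cuffdiff gene table, and the conditions are named only by number. Nothing in the labels says which is Control, so its 2 columns of FPKM per condition were not used, and no direction was taken from it. The test status in that table was OK for 14720 of 39977 rows, not tested for 25250, too deep to estimate for 4 and failed for 3. Its fold changes were not used either, since some of their cells were damaged by a spreadsheet.

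Gene symbols were assigned by identifier from the GENCODE M21 reference for 37605 of the identifiers and from the files for 45, and 1521 remained without a symbol. A second identifier in the library files differed from the first in 104 rows, and 24 names had been turned into dates; the first identifier was used throughout. Positions are those of GENCODE M21 on GRCm38.

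FPKM is not a count, so no count test was run. Values were tested as log2(FPKM + 1), with no further scaling, for genes with a mean FPKM of at least 1 over the 6 libraries. Fold changes on this scale understate the change of low genes. The test was limma 3.58.1 in R 4.3.3 (linear model, eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Tested on simulated data with the spread of these libraries (AngII against Control, 11431 genes, 50 genes changed at each size), the same code recovered 42% of genes changed by 0.5 on the log2 scale, 76% at 1, 98% at 2 and 98% at 3, with 10 false calls. Only genes above 0 in all 6 libraries were simulated, and changes were given only to those of higher expression. The simulated genes varied independently of each other. Recovery of low genes, or of genes that vary together, was not measured. All changed genes stood in the same simulation, and the adjustment is milder where many genes differ. Recovery where few genes differ would therefore be lower, and it was not measured. Of the genes past the threshold, 1 is not reported here. An exact 0 can be a failed estimate in these files, so genes listed at 0 are given as library values.

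Gene lists were tested with camera of limma on the same fit, with a preset correlation between genes of 0.01, Benjamini-Hochberg adjustment over 41 lists, and at least 5 measured genes per list. Of the lists, 11 covered markers of other spleen cells. The other 30 covered T cell states and cell functions, except the immediate early and stress list, which was set up as a technical list. Camera was repeated with a correlation estimated from the data, and fry, which asks whether the genes of a list move one way on balance, was run beside it. Of 946 listed genes, 937 were matched to the files. The mean log2(FPKM + 1) of each list per library was compared by an exact permutation test (two-sided; 3 libraries against 3 cannot go below p = 0.1). Agreement of the libraries was described by Pearson correlation of log2(FPKM + 1) and by principal components. Further tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

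The lists, the tests and the rule for the genes named were chosen before the data were examined. The rule took up to 12 genes higher and 12 lower with the largest fold change among genes past the threshold whose groups did not overlap, filled up where fewer passed with non-overlapping genes of the smallest unadjusted p, which are said not to pass. It left out predicted genes, clone names, small RNAs, pseudogenes and antigen receptor segments, and it added up to 4 genes of smallest p per list, together with Cd4, Cd3e, Cd8a, Foxp3, Agtr1a, Agtr1b, Agtr2, Esr1, Esr2, Gper1, Nr3c1 and Xist. Genes named from the authors' table, and Elane and Fos, were chosen after their values were seen.

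Alternatives were another pseudocount (0.1 or 5), no filter or a mean FPKM of at least 5, median-of-ratios, quantile and equal-sum scaling, eBayes without trend or robust, library weights, the replicate number as a block, a threshold of 0.1, and leaving out each library. Leaving out genes listed at 0 in a whole group was added after the data were seen. Gene lists were not repeated with a pseudocount of 5, a mean FPKM of at least 5, equal sums or a threshold of 0.1. They were also not repeated with eBayes without trend or robust, or with library weights. The number of reads per library is unknown. Steps between low FPKM values gave a depth relative to Control replicate 1 of 1.04, 1.12, 1.07, 1.11 and 1.02 in the other libraries (Control 2 and 3, AngII 1 to 3). The search began from 5771 to 5866 genes below 1 FPKM and kept only small ratios between libraries. It could therefore not have found a large difference in depth, and similar depth is not shown. No intervals for counting error were computed, because they need read counts.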

Results

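CD4+ T cells were isolated from the spleens of female C57BL/6 mice of premenopausal age and their messenger RNA was sequenced. Angiotensin II, the peptide of the renin-angiotensin system that raises blood pressure, was infused at 800 ng/kg/min by osmotic minipump for 14 days from 10 weeks of age. The AngII and Control groups had 3 mice each, with 1 library per mouse. The comparison asks which transcripts of CD4+ T cells respond to a hypertensive stimulus in females that still have ovarian function. Summed FPKM per library lay between 613674 and 717286, and 11438 to 11757 genes reached 1 FPKM. No pair of libraries was a duplicate, since at least 89% of genes differed between any of them.

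The libraries carried the transcripts of helper T cells at similar levels in both groups. Cd4, the co-receptor used for isolation, was at 228.6 ± 25.5 FPKM in Control and 228.1 ± 12.5 in AngII (SD, n = 3). Cd3e, a chain of the T cell receptor complex, was at 505.2 ± 35.6 and 479.3 ± 39.7 FPKM. Cd8a, the marker of cytotoxic T cells, was at 0.855 ± 0.194 and 0.873 ± 0.696 FPKM. Transcripts of other spleen cells were also present, with Ighm of B cells at 784 ± 226 and 720.5 ± 180 FPKM, Hmox1 of macrophages at 468 ± 148 and 625 ± 315, and Vcam1 at 160 ± 26.4 and 232 ± 95.1 (SD, n = 3). Xist, expressed from the inactive X chromosome of females, was at 10.1 ± 2.64 and 8.96 ± 3.13 FPKM. Correlations of log2(FPKM + 1) were as high between groups (mean r = 0.923 over 9 pairs) as within them (mean r = 0.9248 over 6 pairs). The first 3 principal components held 23.1%, 21.9% and 21.2% of the variance, and none of the first 2 parted the groups.

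Few transcripts differed between AngII and Control. Of 11842 genes tested, 4 passed the limma threshold, all lower in AngII, among them the mitochondrial genes mt-Co2 (cytochrome c oxidase subunit) and mt-Nd4 (complex I subunit), and Fam220a. No gene passed as higher in limma (0 of 11842), against 73 genes higher and 135 lower at an unadjusted p under 0.05, 208 in all where chance gives 592. With 1 library left out, some genes passed limma as higher: 5 of 9 without AngII replicate 3, 2 of 7 without Control replicate 3, 2 of 6 without AngII replicate 2 and 1 of 4 without AngII replicate 1. The count at an unadjusted p under 0.05 also moved, to 912 of 11765 without AngII replicate 2 (chance gives 588), 413 without Control replicate 3, 121 without AngII replicate 1, 116 without Control replicate 2 and 2046 of 11842 with library weights, so it is not below chance in every setting. Most genes hardly moved: 91.9% had a log2 fold change within 0.25 of 0, and the median was -0.004. Groups did not overlap for 691 genes (5.8%), where chance gives 10% for 3 against 3. The median 95% interval reached 0.263 to either side of the log2 fold change, and 0.22 for the 6703 genes with a mean of at least 10 FPKM.

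mt-Co2 and mt-Nd4 were listed at 0 in every AngII library. mt-Co2 (ENSMUSG00000064354, chromosome MT, 7013 to 7696, a single exon) was at 17632, 16624 and 15408 FPKM in Control replicates 1, 2 and 3. mt-Nd4 (ENSMUSG00000064363, chromosome MT, 10167 to 11544) was at 6248, 5454 and 5582 FPKM in the Control libraries, and its start overlaps mt-Nd4l. In the authors' deposited table both genes were tested and neither was significant: p was 0.3744 for mt-Co2 and 0.2016 for mt-Nd4 together with mt-Nd4l, from the authors' own test. Other genes used by every cell, such as Eef1a1 and mt-Co1, were listed at 0 in all 6 libraries. Unlike mt-Co2 and mt-Nd4, these 2 have the status too deep to estimate in the authors' deposited table.

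Fam220a (ENSMUSG00000083012, chromosome 5, 143548708 to 143564531) was at 17.1 ± 1.70 FPKM in Control and 3.04 ± 0.726 in AngII (SD, n = 3), with a limma log2 fold change of -2.17 (SE 0.147, adjusted p = 0.0172). The authors' deposited table lists it with a p of 0.3071 and q of 0.999918 from the authors' own test. GENCODE M21 annotates 2 overlapping genes of this name at the locus, of which the library files hold 1. Its limma adjusted p rose above the threshold without Control replicate 1 (0.0692), 2 (0.110) or 3 (0.0601) or AngII replicate 1 (0.145). Without the genes listed at 0 in a whole group, 1 gene passed limma, and without Control replicate 1, Control replicate 3 or AngII replicate 3 the count was 8, 7 and 9.

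**Figure D1:**
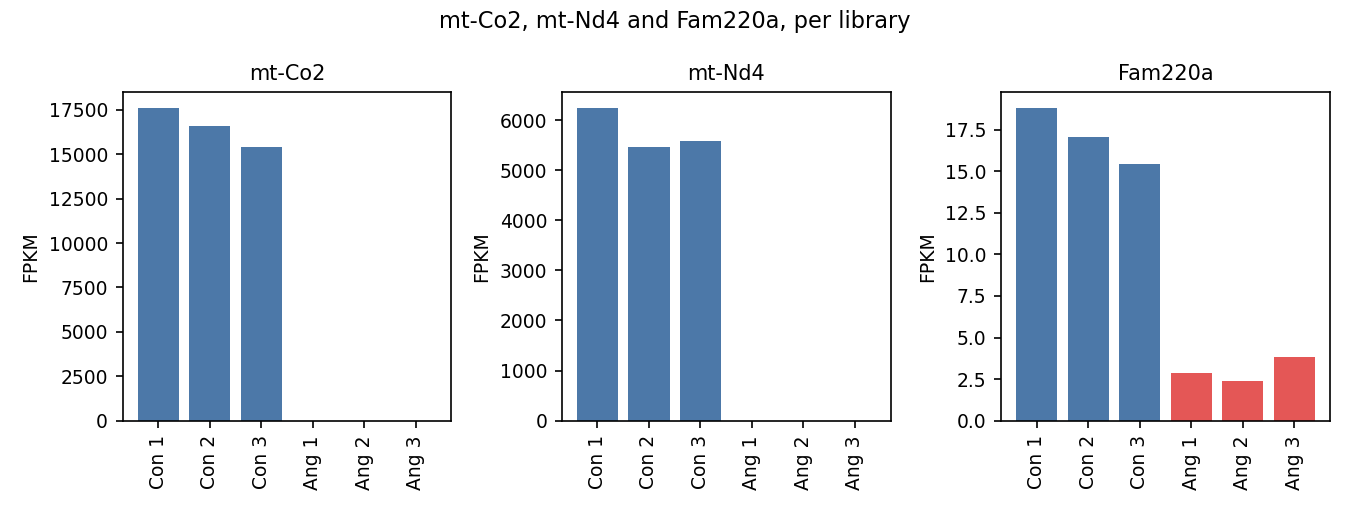
FPKM of mt-Co2, mt-Nd4 and Fam220a in the 6 libraries (blue Control, red AngII; FPKM on the vertical axis from 0). mt-Co2 and mt-Nd4 stand at 0 in the 3 AngII libraries.

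Below the threshold, the genes with the smallest p among those whose groups did not overlap had small differences. Pink1, a kinase that marks damaged mitochondria for removal, was at 48.6 ± 0.976 FPKM in Control and 62.7 ± 2.34 in AngII (SD, n = 3), a log2 fold change of 0.36 that did not pass (limma adjusted p = 0.713). Foxn3, a forkhead repressor, had a log2 fold change of 0.39, and Slc6a6, the taurine transporter, 0.25. Proser3, Ppp2r3d, Ermp1, Rpap2, Mbtps2, Inpp5a, Lmna, Mtmr1 and Nrde2 had log2 fold changes between 0.19 (Mtmr1) and 0.45 (Proser3), none past the threshold. On the lower side, the ubiquitin ligase gene Ubr4 was at 33.8 ± 1.83 and 25.2 ± 0.607 FPKM (SD, n = 3; log2 fold change -0.41, limma adjusted p = 0.713). Psmb9, an immunoproteasome subunit, had a log2 fold change of -0.25, and Socs3, an inhibitor of cytokine signalling, -0.24. Tmsb15b1, Nt5m, Tmem208, C2cd3 and Myl12a had values between -0.58 (Tmsb15b1) and -0.23 (Myl12a). All of these except Pink1 and Ubr4 had a limma adjusted p of 0.9999.

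Receptors through which angiotensin II or estrogen could act directly were listed at low values or at 0. Agtr1a, the main angiotensin II receptor, was at 0.0811 ± 0.0422 FPKM in Control and 0.117 ± 0.0679 in AngII (SD, n = 3), while Agtr1b and Agtr2 were listed at 0 in all 6 libraries. A 0 in these files can be a failed estimate, so by itself it does not show that a receptor was absent. Eef1a1 is no example for the receptors, since the authors' deposited table marks it as too deep to estimate. Esr1, the estrogen receptor alpha gene, was at 0.857 ± 0.273 and 0.912 ± 0.172 FPKM, under the filter. Esr2 and Gper1 stayed below 0.04 FPKM in each library. Nr3c1, the glucocorticoid receptor, was at 40.3 ± 1.84 and 39.9 ± 4.37 FPKM. None of the renin-angiotensin list (9 genes measured), the steroid receptor list (12) or the estrogen-responsive list (17) had a gene past the threshold, over all genes or adjusted over the list alone. Their camera adjusted p were 0.736, 0.918 and 0.257, with mean log2 fold changes of 0.002, -0.004 and -0.034. Within the renin-angiotensin list, Ace was at 1.81 ± 1.36 FPKM in Control and 0.614 ± 0.338 in AngII, and Ctsg, also a granulocyte marker, at 1.19 ± 0.851 and 3.402 ± 2.60 (SD, n = 3). Both are significant in the authors' deposited table (q = 0.0216), without passing limma. Agtrap, which binds the angiotensin receptor, had a log2 fold change of 0.14 without passing, and Igfbp4, an estrogen-responsive gene, one of -0.20.

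Among lists of helper T cell subsets, Th1 passed camera as lower (mean log2 fold change -0.16, camera adjusted p = 0.00158, and adjusted p = 0.713 with an estimated correlation), and the others did not pass. Without Control replicate 3 or AngII replicate 2 the Th1 call was lost (-0.023 and -0.153), and without Control replicate 1 the mean was -0.296. The Th1 level was 4.248, 4.515 and 4.792 in Control replicates 1 to 3 and 4.302, 4.344 and 4.429 in AngII. CD8 T cell markers lay at 3.795, 4.003 and 4.171 in Control and 3.682, 3.695 and 3.931 in AngII. NK markers lay at 3.087, 3.432 and 3.718, and at 3.231, 3.203 and 3.424. Each of these lists rose from Control replicate 1 to 3. Whether RNA of these cells adds to the Th1 values was not tested. Foxp3, the regulatory T cell factor, was at 28.3 ± 2.02 FPKM in Control and 26.6 ± 1.59 in AngII (SD, n = 3; log2 fold change -0.09, limma adjusted p = 0.9999). The regulatory T cell list (26 genes) had a mean log2 fold change of -0.043 and a camera adjusted p of 0.192. Capg from this list had -0.19 and Entpd1 0.47, neither past the threshold. The Th2 (0.014), Th17 (0.010), follicular helper (-0.075), exhaustion (-0.021) and T cell receptor signalling (-0.031) lists also did not pass, with camera adjusted p from 0.13 to 0.736. Further lists that did not pass were glucocorticoid-responsive genes, unfolded protein response, cell cycle, glycolysis and hypoxia, oxidative stress, histone and chromatin modifiers, RNA splicing, salt sensing and ion transport, and apoptosis and p53. Their mean log2 fold changes lay between -0.047 (unfolded protein response) and 0.049 (cell cycle), and their camera adjusted p between 0.07 (cell cycle) and 0.728.

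Of the 41 lists, 17 passed camera with the preset correlation, 14 lower and 3 higher in AngII, and 0 passed with an estimated correlation. With fry, 1 passed, the mitochondrial genome, whose mean rests on mt-Co2 and mt-Nd4, listed at 0 in AngII. Fry was not repeated without these genes. All 76 ribosomal protein genes had lower values in AngII, with a mean log2 fold change of -0.125 (SD over genes 0.042, camera adjusted p = 2e-16), and the call was lost with an estimated correlation (adjusted p = 0.713). Of 55 nuclear genes of oxidative phosphorylation, 53 had lower values (mean -0.10, camera adjusted p = 5.72e-10), and this call was also lost with an estimated correlation (adjusted p = 0.713). Rpl39 and Rps20 had log2 fold changes of -0.20 and -0.13, and Atp5l and Cox7c -0.33 and -0.14, none past the threshold for single genes. With quantile normalization the ribosomal mean was -0.028 and the call was lost. Without AngII replicate 1 the means were -0.067 for ribosomal and -0.045 for oxidative phosphorylation genes, and without Control replicate 2 -0.080 and -0.062. Without AngII replicate 2 the oxidative phosphorylation mean was -0.159.

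Interferon-response genes were lower in AngII as a list: 27 of 29 had lower values, with a mean log2 fold change of -0.11 (SD over genes 0.102, camera adjusted p = 1.04e-05). The call was lost with an estimated correlation (p = 0.0108, adjusted p = 0.442). Ifit1 was at 13.3 ± 0.848 FPKM in Control and 11.6 ± 0.0739 in AngII, and Isg15, a ubiquitin-like interferon product, at 22.3 ± 2.53 and 19.0 ± 1.60 (SD, n = 3). Xaf1 and Ifi27l2a had log2 fold changes of -0.22 and -0.22, and no member passed singly, over all genes or adjusted over the list alone. The list mean was lower in each AngII library (4.050, 3.996 and 4.102) than in each Control library (4.171, 4.171 and 4.148), which gave the smallest possible p of 0.1 in an exact permutation test. By chance 10% of lists reach this p, and 41 lists were tested.

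Further lists passed as lower, among them the immediate early and stress list, which was set up as a technical list. The 27 immediate early and stress genes had a mean log2 fold change of -0.26 (camera adjusted p = 2.65e-05), Th1 genes -0.16 (0.00158), NF-kappaB targets -0.10 (0.00171), effector memory and activation genes -0.11 (0.00367), heat shock genes -0.17 (0.00754), cholesterol synthesis genes -0.12 (0.00107), homing and chemokine receptor genes -0.06 (0.00834) and naive and central memory genes -0.07 (0.0451, with 11 of 20 lower). With an estimated correlation all of these calls were lost, with an adjusted p of 0.713 for each and 0.852 for the naive and central memory list. Among their members, Fos was at 406 ± 225 FPKM in Control and 222 ± 119 in AngII, the Th1 cytokine Ifng at 27.7 ± 2.68 and 19.6 ± 7.76, Tnf at 5.30 ± 0.274 and 4.34 ± 0.527, and the lymph node homing receptor Ccr7 at 342.7 ± 26.3 and 284.8 ± 24.6 (SD, n = 3), none past the limma threshold. Fos was high in 3 libraries of both groups, at 492.8 and 574.9 FPKM in Control replicates 1 and 2 and 357.9 in AngII replicate 2, against 142.9 to 163.8 in the others. The calls of the heat shock (-0.001), cholesterol (-0.026), Th1 (-0.153), homing (-0.045) and naive (0.000) lists were lost without AngII replicate 2. Without Control replicate 3 those of the Th1 (-0.023), NF-kappaB (-0.025), effector memory (-0.049) and homing (-0.019) lists were lost. Further calls were lost without AngII replicate 1 (effector memory, -0.065), Control replicate 1 (naive, -0.031) or Control replicate 2 (naive, -0.046, and cholesterol, -0.063), and with quantile normalization (heat shock, -0.139, and naive, -0.045). Other means moved without losing the call: immediate early to -0.153 without AngII replicate 1 and -0.397 without AngII replicate 2, and NF-kappaB to -0.064 without AngII replicate 1. Without Control replicate 1 the NF-kappaB, Th1 and homing means were -0.163, -0.296 and -0.117. Without AngII replicate 3 the heat shock, homing and naive means were -0.26, -0.099 and -0.140, and without Control replicate 3 the naive mean was -0.145.

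The mitochondrial genome list (8 genes measured) passed as lower with a mean log2 fold change of -3.18, while its median was 0.18 (camera adjusted p = 0.035, and 0.713 with an estimated correlation, where the call was lost). It was also lost with quantile normalization (-3.055), with the replicate number as a block (-3.177), and without Control replicate 1 (-3.125), AngII replicate 1 (-3.144) or AngII replicate 3 (-3.129). The mean rests on mt-Co2 and mt-Nd4, the 2 genes listed at 0, which were also the only members of any list past the threshold adjusted over the list alone. Without them, the other 6 genes had a mean of 0.18, in the opposite direction (camera adjusted p = 8.41e-04, and adjusted p = 0.639 with an estimated correlation), and mt-Nd2 was at 4221 ± 209 FPKM in Control and 4770 ± 383 in AngII (SD, n = 3).

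**Figure D2:**
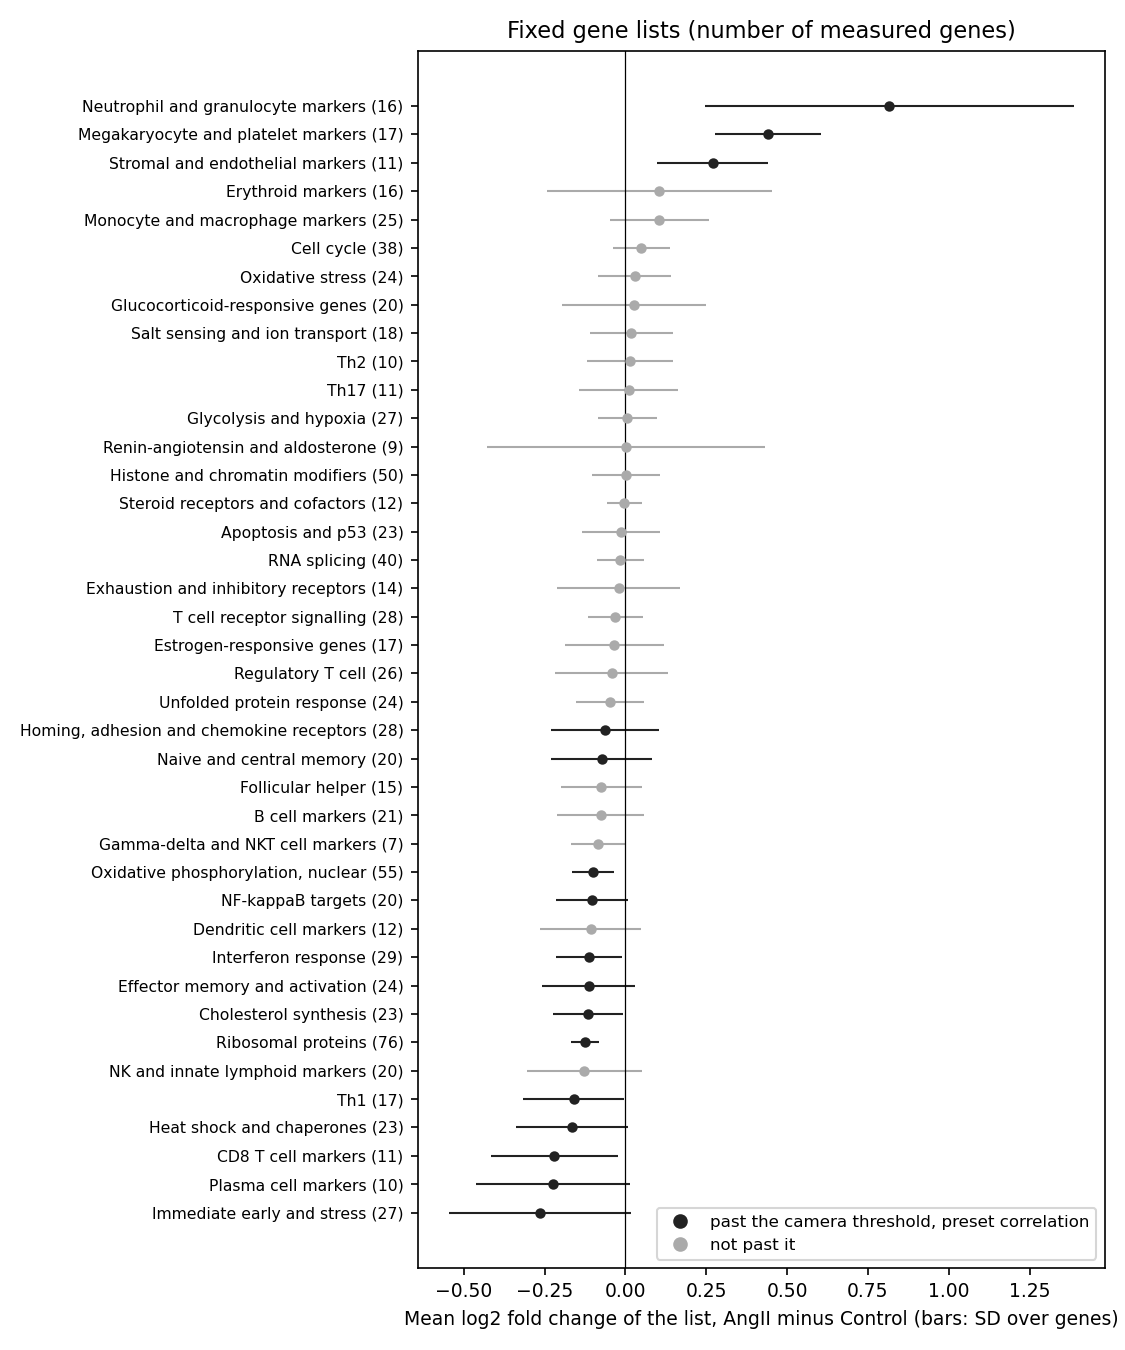
Mean log2 fold change (AngII minus Control, horizontal axis) of 40 gene lists with the SD over genes as bars and the number of measured genes in brackets; black lists passed camera with the preset correlation, and the mitochondrial genome list is left out of the plot. Granulocyte markers lie highest at 0.82 and immediate early genes lowest at -0.26.

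Markers of other spleen cells moved beside these lists. Neutrophil and granulocyte markers were higher in AngII (13 of 16 genes, mean log2 fold change 0.82, camera adjusted p = 2.53e-07), as were megakaryocyte and platelet markers (17 of 17, 0.44, 5.26e-06) and stromal and endothelial markers (10 of 11, 0.27, 2.84e-04). CD8 T cell (-0.22, 0.00608) and plasma cell (-0.22, 0.0142) markers were lower, and all 5 calls were lost with an estimated correlation (adjusted p = 0.713 for each). The neutrophil alarmin S100a8 was at 4.71 ± 4.63 FPKM in Control and 17.1 ± 10.1 in AngII, the granule enzyme Mpo at 4.83 ± 4.01 and 13.2 ± 8.13, and the platelet chemokine Ppbp at 64.7 ± 40.5 and 88.1 ± 15.8 (SD, n = 3), none past the limma threshold. Lists of B cells, NK cells, monocytes and macrophages, dendritic cells, erythroid cells, and gamma-delta and NKT cells did not pass, with mean log2 fold changes of -0.077, -0.127, 0.104, -0.108, 0.105 and -0.086. Without AngII replicate 2 the granulocyte (0.613), stromal (0.076) and CD8 T cell (-0.183) calls were lost and 2 of the 11 lists passed. The platelet mean was 0.212, 0.268 and 0.843 without Control replicate 1, 2 and 3. Without Control replicate 1 or AngII replicate 3, 9 and 8 passed, and without Control replicate 3 the CD8 T cell (-0.129) and plasma cell (-0.013) calls were lost. The plasma cell call was also lost without AngII replicate 1 (-0.085), and its mean was -0.367 without AngII replicate 2. Without a filter on low values the stromal mean was 0.176.

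**Figure D3:**
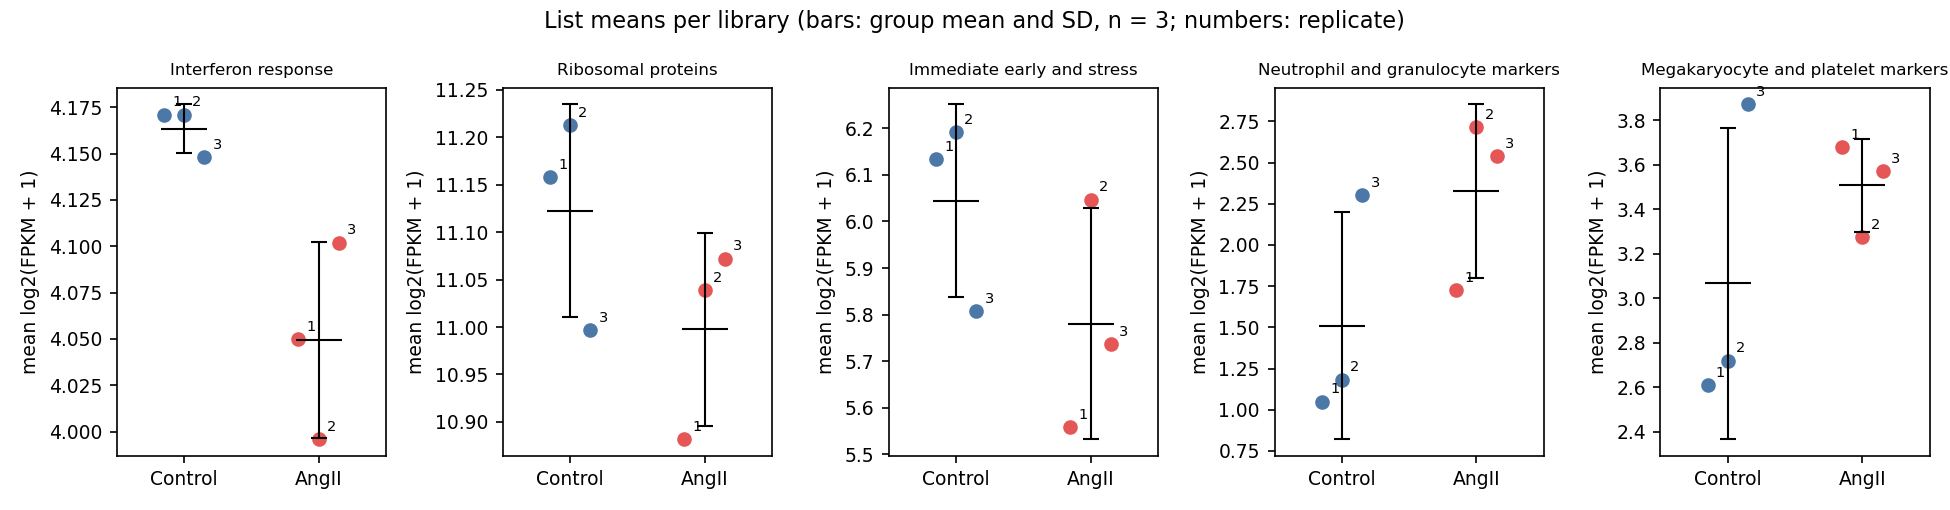
Mean log2(FPKM + 1) of 5 gene lists per library (points, numbered by replicate), with the group mean and SD as bars (n = 3). Interferon-response genes lie lower in all 3 AngII libraries, while granulocyte and platelet markers are low in Control replicates 1 and 2 and high in Control replicate 3.

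The authors' deposited table calls 37 genes significant between its 2 conditions, and the smallest q in the authors' deposited table is 0.0216. Its conditions are named only by number, so no direction was taken from the authors' deposited table. Of these rows of the authors' deposited table, 9 are immunoglobulin segments, 8 are granulocyte markers and 3 are immediate early genes. In the libraries, the means of all 8 granulocyte markers were higher and those of all 3 immediate early genes lower in AngII. Of 33 such genes with library values, 20 had a higher and 13 a lower mean in AngII. The libraries of the groups did not overlap for 3 of the 33 (9.1%): Apol7c, Cdk5rap1 and Cd163. The 10% that chance gives for unselected genes is no measure for the 33, since a test of the same series selected them. Apol7c and Cdk5rap1 had an unadjusted limma p under 0.05 and 0 of 32 tested passed after adjustment. None of the 31 genes called in the authors' deposited table and testable in both was among the 3 genes that limma called there (overlap 0, Fisher's exact p = 1), where chance gives 0.0094, so the count shows neither agreement nor its absence.

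Of the 8 immunoglobulin segments called in the authors' deposited table that have library values, 6 had their highest value in AngII replicate 2, and 1 library held 58.3% to 94.5% of the summed FPKM of each. Rabggtb and Apba3 are significant in the authors' deposited table (q = 0.0216 for both), whereas limma on the libraries did not call them. Rabggtb was at 15.8 ± 0.69 FPKM in Control and 16.5 ± 1.15 in AngII, and Apba3 at 11.2 ± 0.56 and 10.8 ± 1.15 (SD, n = 3). Rabggtb contains small nucleolar RNA genes and Apba3 overlaps Tjp3 and a microRNA gene.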

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

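The number of genes past the limma threshold stayed between 3 and 6 under all planned settings with 6 libraries except without a filter on low values (7), and it was 1 without the genes listed at 0 in a whole group, an alternative chosen after seeing the data. At an adjusted p under 0.05 all of these were lower. Leaving out 1 library gave 4 to 9 genes, of which 0 to 5 were higher. The number of gene lists was 0 with an estimated correlation and 1 with fry, and leaving out 1 library gave 10 to 21. For lists of other cells, for which no alternatives had been planned, these were 0, 0 and 2 to 9. The cause of these changes was not tested. The mean correlation between groups was 0.883 with a pseudocount of 0.1 and 0.881 for genes with a mean FPKM of at least 5, settings chosen after seeing the data. The planned q threshold of 0.01 for the overlap with the authors' calls tests nothing, since 0 genes of the authors' deposited table are below it. A count-based test was planned for the case of read counts and was not run.

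With the replicate number as a block, 3 genes, 21 lists and 8 lists of other cells passed. Libraries with the same number did not deviate together (correlations -0.08 to -0.023, and 0 libraries correlated best with their own number), so the numbers were not read as pairing.

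The mitochondrial genome list, at -3.177, had a mean of 0.181 without genes listed at 0, since mt-Co2 and mt-Nd4 then leave it. The heat shock and plasma cell means kept their sign but were tested by camera on the higher side of the other genes in 1 setting each, without AngII replicate 2 (heat shock, -0.001) and without Control replicate 3 (plasma cell, -0.013); with 1 library left out their means ranged down to -0.26 and -0.367. Some gene values changed sign, and the cause was not tested. With 1 library left out, Cd4 ranged from -0.081 to 0.080 (-0.030 without AngII 1 and -0.011 without AngII 3), Nr3c1 from -0.074 to 0.075, Xist from -0.411 to 0.051 and Apba3 from -0.123 to 0.018. Nr3c1 was at 0.006 with quantile normalization, 0.051 with equal sums, 0.044 with library weights, and 0.007 and 0.075 without Control 1 and AngII 2. Xist was at 0.123 with weights and 0.003 and 0.051 without Control 1 and AngII 2. Rabggtb was at -0.025 with weights, and Apba3 at 0.006 with equal sums, 0.052 with weights and 0.018 without AngII 2. Ighm ranged from -0.296 to 0.11 with 1 library left out (0.065 without AngII 1), and Hmox1 from -0.025 without AngII 2 to 0.577, with -0.036 under library weights.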

Other observations

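All tests in this part were chosen after the result was seen, except those on the abundance of oxidative phosphorylation and interferon-response genes.

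A group of MHC class I antigen presentation genes was put together after some of its members had been seen to be lower. Of its 18 members, 17 had lower values in AngII, a count that the choice of members partly fixed. The mean log2 fold change was -0.10 (SD over genes 0.056), against -0.062 for genes of the same abundance, and none of the members is in the interferon-response list. Psme2, an activator of the proteasome, had -0.19, Nlrc5, the transcriptional activator of MHC class I genes, -0.18, and Psmb10, an immunoproteasome subunit, -0.16. Among 304 tested genes with a log2 fold change beyond 1 in either direction, 69 were immunoglobulin or T cell receptor segments and 220 were small RNAs, predicted or unnamed genes. The other 15 included Fosb (-1.10), Mpo (1.35), S100a8 (1.75), Elane (1.12) and Ngp (1.37).

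The zeros of mt-Co2 and mt-Nd4 in the AngII libraries and the lower Fam220a may come from the estimation of FPKM. In the authors' own test p is 0.374 for mt-Co2 and 0.202 for mt-Nd4 with mt-Nd4l, as failed estimates in the library files predict. The same 2 values argue against a fall to 0 after Ang II, but not against a smaller difference. The median log2 fold change of 0.18 over 6 other mitochondrial genes argues against less mitochondrial RNA. Fam220a has a p of 0.307 in the authors' deposited table, so its difference may also belong to the library files, which list 1 of 2 overlapping gene models, although a p above the threshold does not show equal levels. Which step of the authors' processing gave these values stays open.

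Granulocyte and platelet markers may differ because the preparations held different amounts of these cells. Genes of each list varied together between libraries of the same group, with an inter-gene correlation of 0.64 for granulocyte and 0.84 for platelet markers, but ribosomal protein genes reached 0.857, so this does not single out cell amounts. S100a8 was at 2.53, 1.56 and 10.0 FPKM in Control and 5.75, 20.3 and 25.2 in AngII, and Ppbp at 39.9, 42.9 and 111.4 in Control and 103.4, 71.9 and 89.0 in AngII. The magnetic CD4 isolation should remove both cell types. Whether Ang II raised their number in the spleen or the isolation left more of them was not tested and stays open.

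The small lower shift of abundant transcripts and the interferon-response genes may have separate sources. The 51 other nuclear genes with a mean of at least 500 FPKM had a median log2 fold change of -0.083, and 40 of them were lower, so the ribosomal shift may belong to abundant transcripts in general. Genes of the same abundance as the oxidative phosphorylation genes had a mean of -0.039, between the bounds set for either answer, so the 2 explanations cannot be told apart for them. For interferon-response genes that mean was -0.013, which argues against abundance as the cause of the list's -0.11. Whether the interferon-response list differs beyond chance, and what would lower it, stays open.

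The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 4 genes and the highest other split 3, and 1 of the 10 splits, the real one, called as many genes. This rank rests partly on mt-Co2 and mt-Nd4, whose zeros may be failed estimates. Without genes listed at 0 in a whole group, 1 gene passed in the real split. The real split called 17 lists and the highest other split 22, with 6 of the 10 splits calling as many. The split of Control replicate 1 with AngII replicates 1 and 3 gave 2247 genes at an unadjusted p under 0.05 in limma against 208 for the real one, and that of Control replicates 1 and 2 with AngII replicate 2 gave 1050. These are the highest counts, and the lowest was 143, for Control replicate 1 with AngII replicates 2 and 3. The samples may have a structure other than the groups, which was not tested.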
